A study of Mus musculus with 6 samples.

How the data were processed

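Each of 6 T cell samples, CD69+ and CD69- cells of naive, tolerant and rejecting mice, was measured on 1 single-colour Illumina MouseWG-6 BeadChip array with biotin label from 0.55 µg of total RNA, per the labels' protocols. Group membership was taken from the sample titles. Slide and hybridization date are not given in the sources used here, so no batch could be tested.

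The deposited non-normalized table holds, per the file headers, the signal intensity of each of 45281 probes and a detection p-value per probe and array. The intensities are linear, not background subtracted and not scaled between arrays. Array medians ran from 161.5 to 174.2. The authors' detection p-values are multiples of 1 over 936, which gives the number of negative controls behind them. Data analysis by the authors used GenomeStudio 2009.2, per the submitters' processing notes. The authors' value table holds processed intensities: each column has a median of 168.3, all ranks agree between columns within 1%, and the rank correlation with the array's own non-normalized column is 1, so the values are linear and quantile normalized with no background subtraction. The method behind it is not stated. No log ratio is involved, so a direction does not arise.

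Log2 levels were computed with limma 3.58.1 in R 4.3.3 as in neqc: normexp background correction with the negative control mean and SD inferred from the detection p-values, an offset of 16, quantile normalization and log2. Features with a detection p under 0.01 on at least 1 of the 6 arrays were kept. Genes were named from the platform annotation, with symbols checked against a mouse gene table of assembly GRCm38.p6 used for names alone. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 were unlisted and are unnamed here; 34807 matched the gene table. For each symbol the probe with the highest mean level was used, and probes without a single symbol stood on their own, which gave 10687 features, 8347 named and 2340 unnamed. Other detected probes of the same gene moved in the same direction in 93.8% of 2487 pairs at least 1.5-fold apart between CD69+ and CD69- cells, and in 88.6% of 963 pairs for tolerant against naive CD69+ cells.

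CD69+ and CD69- cells were compared with lmFit and eBayes with status as a block, 3 arrays against 3 and 2 residual degrees of freedom. Pairing follows from the design, since each status gave both fractions. Statuses were compared over both fractions in an additive fit with fraction as a block, 2 arrays against 2, again with 2 residual degrees of freedom. Tests were 2-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. P-values measure how a difference varies between statuses or fractions, since no combination was repeated. Within a fraction, differences between 2 single libraries carry no test and were counted at 1.5-fold or more with a non-normalized signal of at least 500 in the brighter library, the signal minimum of the study's candidate criteria. Where a gene was not detected on any array of the dim side, the fold is a lower bound taken against the lowest level of a detected probe on that array or the gene's own level if higher. The count of genes at least 4-fold higher in tolerant CD69+ than naive CD69+ cells follows the same rule, a choice made after the data were seen, and it was 110, 104 of them unnamed probes, with levels below detection taken as measured. The counts of 1.5-fold differences take those levels as measured. On simulated data with the real means over 10687 features and noise from the robust spread of rejecting minus naive differences, the CD69 fit recovered 21 of 67 genes planted at 1.5-fold, 64 of 67 at 2-fold and 66 of 66 at 4-fold. The tolerant against naive fit recovered 2 of 67, 46 of 67 and 66 of 66. The single-library count for tolerant against naive CD69+ cells recovered 30 of 67, 64 of 67 and 66 of 66 with 405 false calls, and the tolerance criteria 12 of 67, 60 of 67 and 66 of 66 with 35 false calls. In these last simulations every feature was taken to pass the signal minimum. The simulations with no status effect, 100 in number, used the same noise with the signal minimum applied.

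Fixed before the data were examined were the designs, 28 gene lists for T cell programs and for cells that a CD3 sort could still hold, and the alternatives: the authors' value table (values under 16 set to 16), no background correction, median centring in place of quantiles, an offset of 50, no detection filter or detection on all 6 arrays, every probe on its own, no block, each pair left out, an intensity trend with robust variance, a 2-fold minimum and no signal minimum. Lists were tested with camera, at a preset correlation of 0.01 and with an estimated one, with adjustment over 28 lists. For single-library differences a list's median was placed among 10000 random lists of the same size matched on mean level. Random lists hold unrelated genes, so the percentile of a list whose genes vary together is no test of status. Named genes follow a rule fixed at the same time: the 10 largest rises and falls among calls with one direction in every pair, the 10 furthest on each side for CD69+ libraries and 5 for CD69- libraries, the 15 candidates with the largest smaller fold, up to 4 members per list with the largest change and any member set against its own change elsewhere, and Cd69, Cd3e, Cd4, Cd8a, Foxp3, Ifng and Il2. Clone and predicted-gene identifiers were left out. Unnamed probes are given individually where they passed a test of status.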

Results

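T cells from 3 kinds of C57BL/6 mice were profiled after meeting donor antigen. Naive mice had received no graft. Rejecting mice carried tail skin from BDF1 donors, an F1 hybrid of C57BL/6 and DBA/2, and were sampled on day 7 without treatment. Tolerant mice carried the same kind of graft, had been given donor cells together with an antibody against CD40L, which blocks a costimulatory signal between T cells and antigen-presenting cells, and were sampled on day 100. Splenic and lymph node T cells were cultured for 20 to 21 h with donor splenocytes depleted of T cells and sorted on CD3 and on CD69, a surface protein that appears within hours of T cell receptor triggering, so that the CD69+ fraction is enriched for donor-reactive cells. Each of the 6 combinations of status and fraction was measured on 1 Illumina MouseWG-6 array, with 12669 to 13469 probes detected at a detection p under 0.01. There is no replicate of any combination, so every error below describes how a difference varied between statuses or between fractions, and the number of arrays limits the precision. After normalization 10687 genes or unnamed probes were compared, of which 8347 had a gene symbol.

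The first comparison asks what distinguishes activated cells from cells that stayed CD69-, over the 3 statuses. Among the largest rises in CD69+ cells were those of cytokine and chemokine genes. Il2, the T cell growth factor, was at least 83.9-fold higher (log2 difference 7.15, SE 0.23, adjusted p = 0.000479, n = 3 pairs in limma). It was not detected in any CD69- library, and where a gene is not detected in any library of the dim side its fold is given as a lower bound. The macrophage-attracting chemokines Ccl3 (at least 53.0-fold, log2 6.62, SE 0.50, adjusted p = 0.00105) and Ccl4 (5.37, SE 0.47), the lymphotactin gene Xcl1 (5.27, SE 0.48) and Ifng (5.26, SE 0.43, adjusted p = 0.00114) rose as well. So did the transcription factor Irf4 (5.27, SE 0.15), the chemokine receptor Ccr8 (at least 17.3-fold, 5.50, SE 0.11), the branched-chain aminotransferase Bcat1 (at least 53.5-fold, 6.65, SE 0.10), Lad1 (at least 18.4-fold, 5.69, SE 0.14) and the lipid transporter Mfsd2a (at least 15.9-fold, 5.27, SE 0.14). The furthest falls were those of the chemokine receptor Cxcr1 (-4.76, SE 0.34, adjusted p = 0.000979), the immediate early gene Fos (-3.74, SE 0.27), Gprc5b (-3.54, SE 0.40), and the PI3-kinase inhibitor Pik3ip1 (-3.39, SE 0.31). They were followed by Itga7 (-3.38, SE 0.40), Cyp2s1 (-3.32, SE 0.16), Nacc2 (-3.25, SE 0.20, at least 5.03-fold), Rflnb (-3.19, SE 0.18, at least 4.62-fold), the IL-7 receptor gene Il7r (-3.10, SE 0.32) and the cell cycle inhibitor Cdkn1b (-2.99, SE 0.13). Gprc5b was not detected in the naive and rejecting CD69+ libraries, so its value takes levels below detection as measured and its size and rank are uncertain.

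Several gene groups fixed beforehand moved largely in one direction between the fractions, and others were mixed. Of 24 measured genes of early T cell activation, 23 rose, among them Zbtb32 (log2 4.72) and Cd83 (4.17), with 1 falling. All 20 measured proliferation genes rose, led by thymidine kinase Tk1 (3.30, at least 4.19-fold), thymidylate synthase Tyms (3.06), topoisomerase Top2a (2.73) and Cdk1 (2.61, at least 3.36-fold). All 18 measured ribosome biogenesis genes rose, including the RNA polymerase I subunit Polr1b (3.49) and Nop2 (2.57). Of 11 cholesterol synthesis genes 9 rose, with Cyp51 at 2.62 and Sqle at 2.27, and 11 of 14 chaperone genes rose, with Hspd1 at 2.55. Among type 1 helper genes 10 of 17 rose and 3 fell. Among type 2 helper genes 8 of 10 rose, including Il3 (5.14, at least 12.2-fold), Il4 (5.01, at least 14.8-fold) and Csf2 (3.82, at least 5.28-fold). Of the regulatory T cell genes, 13 of 18 rose, including Ebi3 (3.41), Tnfrsf9 (2.96) and Il10 (2.52, at least 3.01-fold), with Foxp3 itself at 1.75 (SE 0.25, adjusted p = 0.00362). Tnfrsf9 and other members of this list are also on the early activation list, and Il10 is on the type 2 list. The counts of these lists are therefore not independent. Of 18 genes of naive and quiescent T cells 16 fell and none rose, including Il6ra (-2.78) and Klf2 (-2.60), a factor that keeps T cells resting. Type I interferon response genes fell in 11 of 19 cases and rose in none, with Oasl2 at -2.20, Ifit2 at -2.08 and Ifit3 at -2.04. This fall was small in the tolerant pair. Relative to each gene's mean over the 6 libraries, the list median was -1.26 in tolerant CD69+ and -1.03 in tolerant CD69- cells. It was -0.61 and 0.80 in the naive pair and 0.56 and 1.60 in the rejecting pair. The sort marker Cd69 rose by 1.53 (SE 0.21, adjusted p = 0.00335), while Cd3e (-0.54) and Cd4 (-0.52) fell and the 2 named Cd8a probes were below detection. Mixed lists were those of anergy and inhibitory receptors (10 of 20 rose and 9 fell), cytotoxic effectors (3 of 10 rose and 4 fell) and glycolysis (1 of 13 rose and 6 fell). The list of immediate early and stress genes, which also respond to handling of cells, fell in 10 of 14 cases and rose in 2 (camera adjusted p = 0.0221, and adjusted p = 0.510 with an estimated correlation). All 4 measured erythroid genes fell, the hemoglobin gene Hbb-bt by 2.21, so red cell transcripts were also more abundant in the CD69- libraries (camera adjusted p = 0.0304, and adjusted p = 0.510 with an estimated correlation). All 3 measured genes of gamma delta and NKT cells rose (median 2.24, camera adjusted p = 0.0737, and adjusted p = 0.510 with an estimated correlation). Of the 4 measured plasma cell genes 2 rose and none fell (median 1.55, camera adjusted p = 0.0619, and 0.510 with an estimated correlation).

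In all, 6698 of 10687 genes passed an adjusted p of 0.05 in limma with status as a block, 3161 higher and 3537 lower in CD69+ cells, of which 1624 and 1526 differed at least 2-fold. Adjusted over the list alone, the counts were the same for the activation, proliferation, ribosome, quiescence and interferon lists and 14 of 18 for the regulatory list. By camera with a preset correlation, adjusted p was 1.84e-08 for early activation, 1.35e-07 for proliferation, 2.57e-07 for ribosome biogenesis, 1.28e-05 for quiescence, 0.000362 for regulatory T cell genes and 0.00452 for the interferon list. With an estimated correlation the adjusted p was 0.510 for the first 5 of these and 0.612 for the interferon list. At the preset correlation camera's adjusted p was 0.00134 for cholesterol synthesis, 0.00177 for chaperones, 0.000308 for type 2 and 0.0122 for type 1 helper genes. Each of these lists had a camera adjusted p of 0.510 with an estimated correlation. With array medians centred and no quantile step, 3619 of 6236 calls were higher, against 3161 of 6698.

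**Figure D1:**
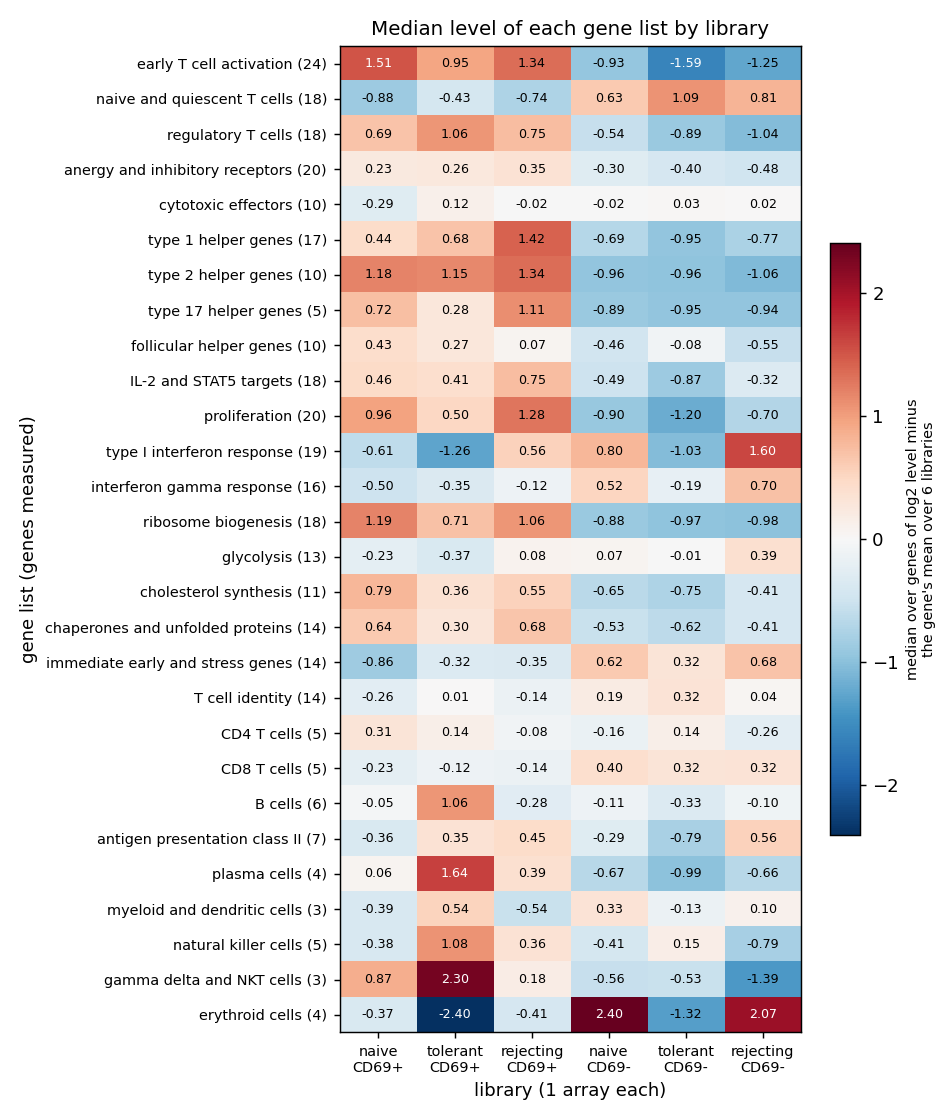
Median level of each of the 28 gene lists in each library, as the median over measured genes (number in brackets) of the log2 level minus that gene's mean over the 6 libraries, with red above and blue below that mean. Early activation stood at 1.51, 0.95 and 1.34 in the naive, tolerant and rejecting CD69+ libraries and at -0.93, -1.59 and -1.25 in the CD69- libraries, while the type I interferon list was lowest in the 2 tolerant libraries (-1.26 and -1.03).

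The second comparison asks whether recipient status left a mark shared by both fractions. The clearest group by camera at the preset correlation, in each of the 3 contrasts, was the type I interferon response. These are the genes that cells switch on when they sense interferon alpha or beta. In each fraction the median of its 19 measured genes was lowest in the tolerant library and highest in the rejecting library. Rejecting exceeded tolerant by a median log2 difference of 2.35, with Oasl2 at 3.65 (SE 0.26), Rsad2 at 3.18 (SE 0.21) and Ifit3 at 2.88 (SE 0.24), and 18 of the 19 genes rose adjusted over the list alone, although none did over all genes tested (Oasl2 adjusted p = 0.0855). Tolerant lay below naive by a median of -1.32, with 12 genes falling adjusted over the list alone and none over all genes, and rejecting lay above naive by 1.03, with 10 rising adjusted over the list alone and none over all genes. Camera's adjusted p for this list was 1.94e-23, 2.45e-15 and 1.06e-18 for the 3 contrasts with a preset correlation, and adjusted p = 0.526, 0.528 and 0.916 with an estimated correlation. Hemoglobin genes moved beside the interferon genes in the tolerant libraries but not in the rejecting ones: Hbb-bt differed by -3.03 (SE 0.44) between tolerant and naive and by -0.21 (SE 0.44) between rejecting and naive. The 4 measured erythroid genes lay further below naive in tolerant cells (median -2.90), and all 4 fell adjusted over the list alone. Early activation, proliferation, and IL-2 and STAT5 targets were also lower (camera adjusted p = 3.91e-06, 3.91e-06 and 5.71e-06 at the preset correlation). Quiescence genes were higher (camera adjusted p = 0.000409). With an estimated correlation adjusted p was 0.528 for each of these lists, and no member passed over all genes.

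Interferon gamma response genes showed a smaller gap, with a median rejecting minus tolerant difference of 0.65 and 6 of 16 rising adjusted over the list alone, none over all genes (camera adjusted p = 2.34e-07, and adjusted p = 0.526 with an estimated correlation). Ifng itself differed by -2.18 between tolerant and naive and by 1.72 between rejecting and tolerant, and neither passed over all genes. Of the 10687 genes, limma with fraction as a block called 1 between tolerant and naive, 0 between rejecting and naive and 2 between rejecting and tolerant, while 1285, 506 and 1530 had an unadjusted p under 0.05 where 534 would be expected by chance. The 3 calls came from 2 unnamed probes. ILMN_1251419 stood at log2 13.95 and 13.25 in the tolerant CD69+ and CD69- libraries and between 5.38 and 5.82 in the other libraries, where it was not detected. ILMN_1246194 was higher in rejecting than tolerant cells (adjusted p = 0.0130), at 9.22 and 11.40 in the rejecting CD69+ and CD69- libraries and 7.90 in tolerant CD69- cells, and was not detected in tolerant CD69+ cells, so the size of the difference is not given. The rejecting against tolerant count reached 87 with an intensity trend and robust variance, of which 13 were among the 19 interferon genes, 23 with the authors' value table and 17 among named genes only, and fell to 0 without the fraction block. The tolerant against naive count ran from 0 to 6 and the rejecting against naive count stayed at 0 over the settings tried, including a fit without the tolerant libraries.

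**Figure D2:**
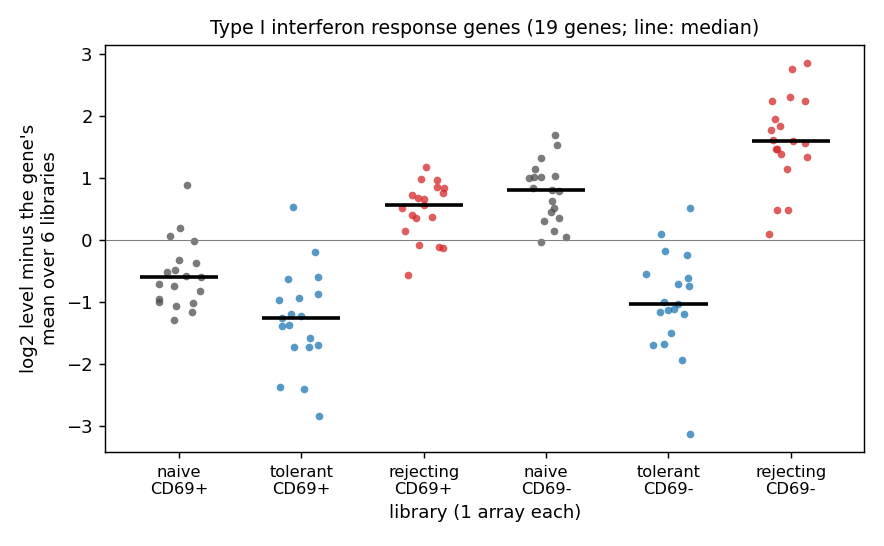
Each point is 1 of 19 type I interferon response genes in 1 library, as log2 level minus the gene's mean over the 6 libraries, and the black line is the library's median. Medians were -0.61, -1.26 and 0.56 in the naive, tolerant and rejecting CD69+ libraries and 0.80, -1.03 and 1.60 in the CD69- libraries.

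Within the CD69+ fraction, each status is 1 library, so the following differences are values with no test. Several cytokine and chemokine genes were lower in CD69+ cells of tolerant mice than in those of naive mice. Ifng was 8.46-fold lower, Ccl3 5.22-fold, Ccl4 3.85-fold and Il2 2.49-fold lower, and Ccl9 at least 4.63-fold lower. The interferon-induced genes Oasl2 and Rsad2 were 3.58-fold and 3.46-fold lower, Nup54 3.79-fold, and the hemoglobin genes Hbb-bt, Hba-a1 and Hbb-bs 4.46-fold, 4.41-fold and 4.05-fold lower. Genes furthest higher in tolerant cells were Mzb1, which B cells and plasma cells express for antibody assembly (14.8-fold), the granule protein gene Prg2 (at least 5.64-fold), Gpnmb (5.57-fold), Dtx4 (at least 4.34-fold), Ahnak (4.05-fold), the linker histone H1f2 (3.96-fold), granzyme K, Gzmk (3.83-fold), transferrin, Trf (3.67-fold), Pde2a (3.56-fold) and Gprc5b (at least 3.03-fold).

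By gene group, early activation, proliferation and ribosome biogenesis were lower in the tolerant CD69+ library. The median log2 difference from naive was -0.33 for early activation, -0.52 for proliferation and -0.52 for ribosome biogenesis, at percentiles 0.14, 0 and 0 among 10000 random lists matched on expression. Members of these lists varied together (estimated correlation 0.15, 0.41 and 0.78), unlike those of random lists. An extreme percentile, here and below, can therefore come from any difference between single libraries. Type 1 helper genes were lower (median -0.35, percentile 0.51), although Ccl5 was higher by 1.80, and the 10 measured cytotoxic effector genes were higher (median 0.41, percentile 98.59, 8 of 10 higher). Genes of naive and quiescent T cells were higher, 16 of 18 of them, with Il7r at 1.77, Klf3 at 1.76, Pik3ip1 at 1.70 and Klf2 at 1.53 (median 0.46, percentile 99.97). Regulatory T cell genes had a median of 0.25 (percentile 97.6), led by Tnfrsf1b at 0.92 and Nt5e at 0.82, and Foxp3 itself differed by 0.58. Measured markers of other cells were also higher. The 6 measured B cell genes, of 18 listed, were so by a median of 1.18 (percentile 99.98, Cd79b at 1.19), and 7 class II antigen presentation genes, of 10 listed, by 0.89 (99.99, H2-Eb1 at 1.34). The B cell markers Ms4a1, Pax5 and Cd22 were below detection on all arrays. The 5 measured natural killer cell genes, of 12 listed, were higher by 0.99 (99.91, Klre1 at least 2.28-fold), the 3 measured genes of gamma delta and NKT cells by 1.29 (99.66, Cd163l1 at 1.43) and the 4 measured plasma cell genes by 0.75 (98.55, 2 of them higher and 2 lower). Blk counts in both the B cell and the gamma delta and NKT lists. Of 10687 genes, 947 were at least 1.5-fold higher and 669 at least 1.5-fold lower with a signal of at least 500 in the brighter library, and with levels below detection raised to the detection limit of their array, 93 of the 98 that were at least 4-fold higher were unnamed probes. Simulations with no status effect gave on average 61.7 genes at least 1.5-fold apart with that signal, and at most 78. Their noise was the robust spread of rejecting minus naive differences, a pair with 218 such genes in CD69+ cells, so they may understate chance. They also gave the tolerant array the same noise as the others, so they cannot separate status from a trait of that array. With array medians centred, the split was 1232 higher and 474 lower.

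Rejecting CD69+ cells differed from naive CD69+ cells at fewer genes than tolerant ones did, and interferon-induced genes were among the furthest higher. Oasl2 was 2.97-fold, Ifit3 2.64-fold, Oasl1 2.61-fold, Usp18 2.42-fold, Samd9l 2.40-fold, Ifi214 2.31-fold and Stat2 2.30-fold higher, beside Pros1 (2.44-fold), Tmie (2.27-fold) and Evl (2.16-fold). The type I interferon list had a median of 1.06, higher than each of the 10000 random lists, with 17 of its 19 genes at least 1.5-fold higher, and the interferon gamma list a median of 0.32. Glycolysis genes were higher by a median of 0.27 (percentile 99.97), led by the lactate exporter Slc16a3, at least 1.59-fold higher. Genes of naive and quiescent T cells were higher here too, by a median of 0.45 (percentile 100), and so were immediate early and stress genes, by a median of 0.37 (percentile 99.99, 12 of 14 higher). Among cell type lists, class II genes were higher (median 0.39, percentile 99.85, 6 of 7 higher) and B cell genes lower (median -0.36, percentile 0.56, 5 of 6 lower), as were the 3 measured genes of gamma delta and NKT cells (median -0.68, percentile 0.07, 2 of 3 lower). The furthest lower were Ccl9 (at least 4.35-fold), the type 17 cytokine gene Il17f (2.83-fold), the B lymphoid kinase gene Blk (2.44-fold), Idi2 (2.35-fold), Bdh2 (2.20-fold), Ccl1 (2.15-fold), Cdk5r1 (1.81-fold), Nfkbib (1.75-fold), Pheta1 (1.72-fold) and Xcl1 (1.71-fold). Ifng, Il2 and Foxp3 differed by -0.32, -0.14 and 0.04. In all, 180 genes were at least 1.5-fold higher and 38 lower, a total of 218 that was 138 with the authors' value table.

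Rejecting and tolerant CD69+ cells were set side by side because the study defines its rejection genes on this pair. Among the 10 genes furthest higher in rejecting cells were the interferon-induced Oasl2 (10.6-fold), Rsad2 (7.46-fold), Ifit3 (6.92-fold), Usp18 (5.06-fold), Isg15 (4.54-fold), Cmpk2 (4.49-fold) and Irf7 (4.33-fold). The others were Ifng (6.77-fold), Cyp11a1 (at least 4.50-fold) and Hbb-bt (4.42-fold). Lower in rejecting cells were Mzb1 (10.1-fold), Prg2 (at least 6.10-fold), Blk (5.96-fold), Gpnmb (5.79-fold), Gzmk (4.92-fold), Gja1 (at least 4.81-fold), Tmem176a (4.62-fold), Kcnk1 (4.41-fold), Slc6a13 (at least 4.11-fold) and Gprc5b (at least 3.28-fold). Proliferation genes were higher by a median of 0.76 and ribosome biogenesis genes by 0.41, both above each of the 10000 random lists, while B cell genes were lower by a median of -1.36 (percentile 0) and natural killer cell genes by -0.82 (percentile 0.19). In number, 508 genes were at least 1.5-fold higher and 695 lower. Across the 3 CD69+ libraries, log2 levels correlated over genes, which are not independent replicates, at 0.992 between naive and rejecting, 0.963 between naive and tolerant and 0.969 between rejecting and tolerant.

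**Figure D3:**
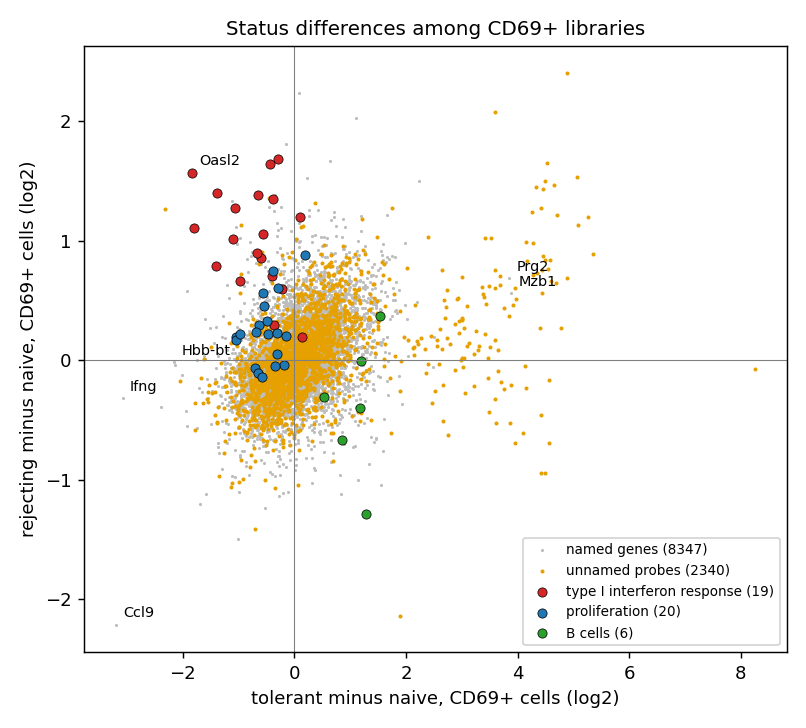
Each point is a gene or unnamed probe, with its log2 difference from the naive CD69+ library in the tolerant (horizontal axis) and rejecting (vertical axis) CD69+ library. Interferon genes (red) lie above 0 on the vertical axis, proliferation genes (blue) lie mostly left of 0 (median -0.52) and B cell genes (green) right of 0 (median 1.18), and unnamed probes (orange) extend to the far right, where Mzb1 and Prg2 lie.

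Among CD69- cells of the 3 statuses correlations over genes ran from 0.985 to 0.992. The tolerant library lay closer to the naive (0.991) and rejecting (0.985) ones than in the CD69+ fraction (0.963 and 0.969). Naive and rejecting libraries correlated at 0.992 in both fractions. Tolerant CD69- cells were lower than naive CD69- cells in hemoglobin genes (log2 -3.90 for Hbb-bt, -3.76 for Hbb-bs and -3.70 for Hba-a1), in the interferon-induced chemokine gene Cxcl10 (9.02-fold) and in Oasl2 (7.09-fold). They were higher in Trnp1 (2.59-fold), Camk2n1 (2.46-fold), granzyme M, Gzmm (2.23-fold), Snora65 (2.14-fold) and Adh1 (2.09-fold). Rejecting CD69- cells exceeded naive ones in Fam240a (4.10-fold), the interferon-induced Mx2 (3.82-fold) and Oas2 (3.57-fold), Aqp9 (3.23-fold) and Rgs11 (2.84-fold). They were lower in Ltb4r1 (3.74-fold), Actn2 (2.66-fold), Asb2 (2.51-fold), Tmem176b (2.45-fold) and Sgip1 (2.17-fold). Against tolerant CD69- cells, rejecting ones were higher in Oas2 (at least 9.28-fold), Oasl2 (14.9-fold), Cxcl10 (12.3-fold), Hbb-bt (11.3-fold) and Rsad2 (11.1-fold). They were lower in Sgip1 (3.78-fold), Ltb4r1 (3.27-fold), Actn2 (3.19-fold), Trnp1 (3.13-fold) and Prss12 (3.09-fold). The type I interferon list stood at a median of -1.79 for tolerant minus naive (percentile 0), 0.93 for rejecting minus naive and 2.84 for rejecting minus tolerant (both at percentile 100), and early activation genes at -0.46 for tolerant minus naive, with Cd69 at -1.32 and Irf4 at -1.41, and at -0.22 for rejecting minus naive (percentile 0, 19 of 24 lower). For tolerant minus naive, class II genes were lower here (median -0.75, percentile 0, 6 of 7 lower) where they were higher in the CD69+ fraction, while quiescence genes (0.15, percentile 99.95) and cytotoxic effector genes (0.21, percentile 99.78) were higher in both fractions. Regulatory T cell genes were lower than naive in both grafted groups, by medians of -0.22 in tolerant (15 of 18 lower) and -0.44 in rejecting CD69- cells (13 of 18 lower), each at percentile 0. Counts of genes at least 1.5-fold apart were 73 higher and 165 lower for tolerant against naive, 130 and 76 for rejecting against naive and 288 and 238 for rejecting against tolerant. With array medians centred these splits were 46 and 225, 68 and 302, and 230 and 361, so the direction of the rejecting against naive and rejecting against tolerant splits turned.

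The study defined candidate tolerance genes as those at least 1.5-fold higher in tolerant CD69+ cells than in naive CD69+ and in tolerant CD69- cells, with a signal of at least 500. Those with the largest smaller fold were Mzb1 (14.8-fold over naive and 25.3-fold over tolerant CD69-), Prg2, Trf (3.67-fold and 8.44-fold), Gpnmb (5.57-fold and 3.19-fold) and the growth factor gene Igf2 (3.17-fold and 5.67-fold). Next came the transporter gene Slc6a13 (3.00-fold over naive), connexin 43, Gja1 (2.94-fold), Sytl2 (2.91-fold), cathepsin H, Ctsh (2.86-fold), Tspan17 (2.83-fold), the matrix protease gene Mmp9 (2.77-fold), Cd163l1 (2.69-fold), the class II gene H2-Eb1 (2.54-fold), Tmem176a (2.53-fold) and the actin-bundling protein gene Fscn1 (2.53-fold). Prg2 was not detected in naive CD69+ cells and was at least 5.64-fold higher. The criteria took 201 features, 86 named genes and 115 unnamed probes (57.2%), of which 184 also met the same criteria with the rejecting library in the place of the naive one. Both lists share the tolerant libraries, and chance gave 3.38 shared genes in simulations that keep them and 4.14 for independent lists. The simulated tolerance lists held 20.0 genes on average, so 3.38 is not on the scale of 201. A trait of the tolerant CD69+ array would enter both lists, so the overlap cannot separate status from such a trait. B cell, class II and natural killer cell markers were higher in the same library, as given above.

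Candidate rejection genes, at least 1.5-fold higher in rejecting CD69+ than in tolerant CD69+ and rejecting CD69- cells, numbered 287, of which 239 were named. They were led by Ifng (6.77-fold over tolerant CD69+), the steroid synthesis gene Cyp11a1 (at least 4.50-fold), Ccl3 (3.98-fold), the mitotic kinase gene Pbk (3.59-fold), and the cytokine gene Lif (3.42-fold). Next came Sema7a (3.36-fold), the DNA repair gene Rad54b (3.22-fold), Cetn4 (3.15-fold), Ccl4 (2.88-fold), Aunip (2.81-fold), the replication genes Mcm10 (2.70-fold), Pclaf (2.66-fold) and Cdc45 (2.39-fold), Crabp2 (2.66-fold) and transglutaminase Tgm2 (3.46-fold over tolerant CD69+ and 2.55-fold over rejecting CD69-). Their level in the naive CD69+ library, which the criteria leave out, was close to that in rejecting cells: the median log2 difference of rejecting minus naive was -0.03, and 11 of the 287 were at least 1.5-fold higher in rejecting cells. Of the 287, 224 (78.0%) also met the criteria with naive in the place of rejecting. Chance with no status effect gave 2.75 shared genes in simulations that keep the shared tolerant library, and independent lists of these sizes would share 14.2, and both lists share the tolerant CD69+ library. The simulated rejection lists held 18.6 genes on average, so 2.75 is not on the scale of 287. Here too a trait of the shared array would enter both lists, so the overlap cannot separate status from it. The same rule run on each ordered pair took 530 for naive over tolerant, 220 for tolerant over rejecting, 31 for naive over rejecting and 24 for rejecting over naive, and simulations with no status effect gave on average 20.0 tolerance and 18.6 rejection genes, with highest counts of 30 and 31. These simulations used the same noise on every array, so they may understate chance for the tolerant one.

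**Figure D4:**
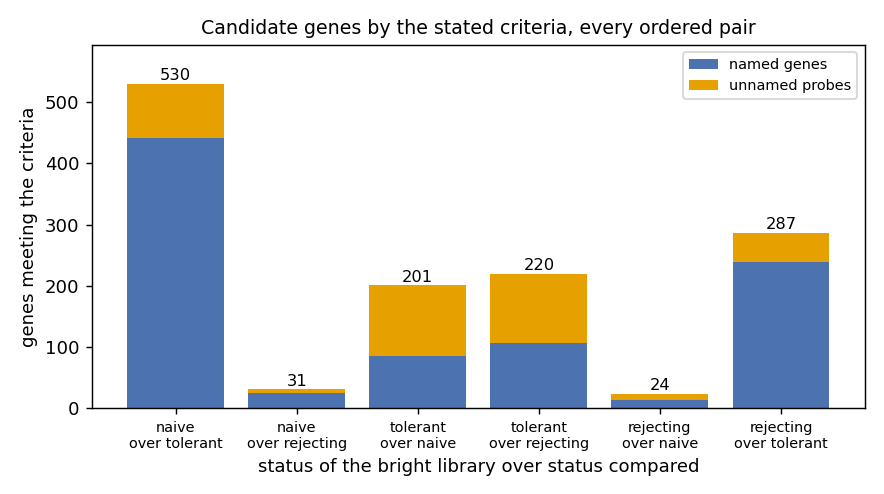
Bars give the number of features that meet the candidate criteria for each ordered pair of statuses, with named genes in blue and unnamed probes in orange, from a baseline of 0. The 4 pairs that involve the tolerant CD69+ library took 530, 201, 220 and 287 features, and the 2 pairs without it 31 and 24.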

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

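All tests of explanations here were chosen after the results were seen. The CD69+ minus CD69- difference of Ahnak, a large scaffold protein gene, was 0.59 on the log2 scale in tolerant cells and -0.70 in naive cells, opposite directions; the difference between statuses was not tested. The median of the 3 measured myeloid and dendritic genes (Fcgr3, Cst3 and Fcer1g) was 0.67 in tolerant cells, -0.72 in naive cells and -0.64 in rejecting cells, and this difference was not tested either. For CD69+ against CD69- cells, the 6 arrays allow only 10 splits into 3 and 3, too few for a share under 0.05; the real split called 6442 genes without the status block, 1 of the 10 splits gave as many, and the highest of the other splits called 0.

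The tolerant CD69+ library stood apart from the other CD69+ libraries, with less proliferation and ribosome biogenesis mRNA. Quiescence genes were above naive by a similar median in the rejecting CD69+ library, so more quiescence mRNA than naive does not set this library apart. Early activation genes were lower than naive in both tolerant fractions. Their median was -0.33 in CD69+ and -0.46 in CD69- cells (20 of 24 lower), so they do not set this library apart. Proliferation and ribosome biogenesis genes were also lower than naive in tolerant CD69- cells. Their medians there, -0.16 (18 of 20 lower) and -0.13 (13 of 18 lower), were smaller than in CD69+ cells (-0.52 for each). For these 2 lists the CD69+ library therefore differs in size and not in direction. The tolerant CD69+ array was not poorer in detected probes, at 13452 the second of the 6 after 13469. Such counts do not measure RNA quality, amplification or hybridization, so a technical cause for this library stays open. A single admixture of CD69- cells as the whole cause is argued against because 416 genes at least 4-fold higher with CD69 in the naive and rejecting pairs imply a share of 34.1% (95% bootstrap interval 31.7 to 36.8), while 173 genes at least 4-fold lower imply 12.1% (10.4 to 13.6), a difference of -22.0 percentage points, or -23.1 with levels below detection raised to the detection limit of their array. The intervals resample genes and hold no variation between libraries. The genes were also picked on libraries that form the reference, so the weight of this gap is limited. A smaller admixture beside another difference stays open, as do the differences in the design, which 1 library per group cannot test. Tolerant mice differed from naive ones by graft, donor cells, antibody against CD40L and time, and these cannot be told apart.

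A set of 105 probes, 101 of them unnamed here, was at least 4-fold brighter in the tolerant CD69+ library than in both other CD69+ libraries when levels below detection are taken as measured; with those raised to the detection limit of their array the set is 94 probes, 91 of them unnamed, and the named ones are Gpnmb, Mzb1 and Prg2. CD69- cells in the sort are argued against, since 98.1% of these probes (98.9% of the 94) were also at least 2-fold above the tolerant CD69- library. Antibody-secreting cells that passed the CD3 gate may contribute, a possibility left open because 2 of 8 plasma cell markers, Mzb1 (log2 3.89 over naive) and Derl3 (1.56), were detected and at least 2-fold above both other CD69+ libraries. Derl3 was undetected in those, so its bound was only 1.13-fold over naive and only Mzb1 is certain to pass, while Irf4 and Xbp1, which T cells also express, were not higher and the named probes of Jchain, Sdc1, Prdm1 and Tnfrsf17 were below detection. No named feature was an immunoglobulin gene, so those could not decide it.

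Type I interferon genes were lowest in the tolerant and highest in the rejecting library of each fraction. Normalization is argued against as the cause, because the smallest of the list medians for rejecting minus naive and naive minus tolerant, over 4 other normalizations and both fractions, was 0.43 on the log2 scale. These 4 are not independent checks: the value table and the setting with no background correction are nearly the same processing. Only median centring drops the quantile step. Red cell carry-over is argued against for rejecting against naive, where hemoglobin genes moved the other way (the larger ratio to the interferon median was -0.41), but for tolerant against naive hemoglobin fell with the interferon genes by up to 3.55 times as much, which leaves a shared cause open. A culture or hybridization batch cannot be told apart from status with 1 library per status and fraction, and neither can the biological difference between recipients, which stays among the open explanations. Treatment and the day after grafting, 100 for tolerant and 7 for rejecting mice, also follow status and cannot be separated from it.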

How the results depend on the processing

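One setting was changed at a time, but the value table changes background correction, offset and floor together, and the trend setting also makes the variance robust; leaving out the tolerant libraries for rejecting against naive and keeping named genes only were chosen after seeing the data. The count of CD69-dependent genes stayed within 1.5 times under each alternative run, from 4589 without the rejecting pair to 7189 without the tolerant pair and 9762 with every probe on its own; without the status block, which drops the pairing, it was 6442 (6237 of them shared with the 6698). Rejecting against tolerant over both fractions went from 2 to 23 with the value table or with no background correction (18 higher, 5 lower), 13 with an offset of 50 (11 higher, 2 lower), 14 with detection on all 6 arrays, 87 with trend and robust variance, 17 with named genes only and 0 without the fraction block; tolerant against naive went from 1 to 0 with detection on all 6 arrays, with named genes only and without the block, and to 6 with trend and robust variance. Where features were left out their own removal ends the call of the 2 unnamed probes; otherwise the cause was not tested. For single libraries, rejecting against naive fell from 218 to 138 (value table) and 137 (no background correction) in CD69+ cells and from 206 to 136 (no background correction) in CD69- cells, and rose to 370 there with medians centred. That setting moved the median difference of all genes by over 0.1 in places (from -0.02 to -0.20 for rejecting against naive CD69- cells, from -0.05 to 0.09 for CD69+ against CD69-) and the share of higher calls from 47.2% to 58.0% (CD69), 58.6% to 72.2% (tolerant against naive, CD69+), 73 of 238 to 46 of 271 (tolerant against naive, CD69-), 63.1% to 18.4% (rejecting against naive, CD69-) and 54.8% to 38.9% (rejecting against tolerant, CD69-). Candidate tolerance genes fell from 201 to 74 with detection on all 6 arrays and to 86 with named genes, and candidate rejection genes rose from 287 to 450 with every probe on its own, as those settings' own feature sets give. By construction a 2-fold minimum gave fewer (tolerant against naive 455 in CD69+ and 84 in CD69-, rejecting against naive 38 and 40, rejecting against tolerant 371 and 181, tolerance genes 129, rejection genes 50) and no signal minimum more (2617, 674, 643, 690, 2018, 1175, 368 and 461, in that order). Under the 4 other normalizations no list median and no single-library difference of a named gene changed direction where it was at least 1.5-fold. In the tested contrasts a change of direction was counted only for a gene passing in either setting, and none was. Of 4096 status values of named genes, 538 moved by at least the gene's own SD in the CD69 fit. That rule was applied only to the single-library differences among them, so 538 is not a share of all 4096. In the tested contrasts 11 values passed under another normalization but not in the main one. Of 1120 list medians, 162 moved by at least the prior SD of the fit (0.165). Dim genes are limited by signal over background: detection p under 0.01 was met by 28.0% to 29.7% of probes per array.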

Other observations

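Sugar-use genes were higher in both rejecting libraries than in the naive ones. In CD69- cells the 13 measured glycolysis genes were higher in rejecting than naive cells by a median log2 difference of 0.27, above each of the 10000 random lists, with the lactate exporter Slc16a3 at 0.79 and the glucose transporter genes Slc2a3 at 0.39 and Slc2a1 at 0.37, as in the CD69+ cells (Slc2a3 0.71, Slc2a1 0.55). Over both fractions camera gave an adjusted p = 2.03e-06 with a preset correlation and adjusted p = 0.861 with an estimated correlation, and 1 of the 13 rose adjusted over the list alone and none over all genes. The stress-induced mTOR inhibitor gene Ddit4 was higher in rejecting than naive cells by 0.96 in the CD69+ and 1.25 in the CD69- fraction. It belongs to the list of immediate early and stress genes, which was higher in rejecting CD69+ cells (median 0.37, 12 of 14 higher) and close to level in CD69- cells (median 0.03, 8 of 14 higher).

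Natural killer cell genes had a median rejecting minus tolerant difference of -0.82 in CD69+ cells (5 of 5 lower) and -0.91 in CD69- cells (4 of 5 lower). Over both fractions 1 of the 5 fell adjusted over the list alone and none over all genes (camera adjusted p = 0.0235, and adjusted p = 0.526 with an estimated correlation). The cytotoxic effector list did not differ as a group, with medians of 0.00 (percentile 48.02) and -0.11 (percentile 21.15). Among members of the cytotoxic list, Gzmk was lower in rejecting than tolerant cells by 2.30 in CD69+ and 1.33 in CD69- cells on the log2 scale, and Klrd1 by 1.18 and 1.01. Klre1, a natural killer receptor gene, stood at least 2.28-fold above naive in tolerant CD69+ and at least 1.96-fold above in tolerant CD69- cells. Adjusted over the list alone, 2 of 10 cytotoxic effector genes fell in rejecting against tolerant cells and none passed over all genes; the list as a whole had a camera adjusted p = 0.410, and adjusted p = 0.644 with an estimated correlation.

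Of 10687 features, 12 differed by CD69 at least 1.5-fold in opposite directions between statuses, and in 7 of them CD69+ cells were higher in the tolerant and lower in the naive pair. None was the other way round between those statuses.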
